A study of Mus musculus with 4 samples.

How the data were processed

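RNA was measured on 4 Affymetrix whole-transcript arrays, 2 of HSCs from WT mice and 2 from mice labelled Hif1a-/-, with total RNA amplified and labelled with biotin per the labels' protocols. The deposited values are log2 signals, made by the authors with RMA in Affymetrix Expression Console 1.1 per the submitters' processing notes. The log base is taken from the range of the values, which lie between 3.08 and 14.88. RMA corrects the background, normalizes the probe signals of the arrays to a common distribution and summarises probes into probe sets. A change shared by all genes would thus be removed before deposit. The deposited probe-set values still differed in spread. Their interquartile ranges were 2.61 and 2.78 in WT arrays 1 and 2, and 2.60 and 2.49 in the arrays labelled Hif1a-/-. A genome build is not given in the sources used here, and no coordinates are printed. Each array was assigned to its genotype by its title and genotype label, and the table held 0 columns of other samples.

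The table had 35556 probe sets. Of these 21789 had exactly 1 gene symbol in the platform annotation, 1621 had several and 12146 were not listed there. Genes were named only from probe sets with 1 symbol. Of these, 21698 were found in the reference gene table by gene ID and 0 symbols had to be updated. Where a gene had over 1 probe set (999 genes), the probe set with the highest mean over all arrays was used, which left 19938 genes. No filter on dim probe sets was applied. Array number, not sequencing depth, limits the precision here.

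The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates). p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Gene lists were tested with camera at the preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over 26 lists. Of 27 lists, the sex-linked genes were given per array and not tested. The lists named 669 genes, of which 603 were matched, and the 66 unmatched ones include Cdkn1a, Trp53, Gapdh and Eno1. Small nucleolar RNAs and histone genes were taken by the start of their symbol. The medians of some lists were set against 10000 random lists of the same size matched on mean signal in 50 bins.

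The named genes are Hif1a, then up to 12 genes per direction past the threshold with no overlap between the groups. As none passed, the places went to the genes with the smallest unadjusted p among those with no overlap, a log2 difference of at least 0.585 and a higher-group mean over the median of all genes. In each list up to 2 members per direction with the smallest p were named. Pax5 and Ebf1 are named as members that passed adjusted over the B cell list alone. Lists, tests, the naming rule and the alternatives were fixed before the data were examined, except the set of immunoglobulin genes, the medians within each array number, the genes named for the difference between array numbers and the tests and gene sets that the closing section names as chosen later. Alternatives were the replicate number as a block, each array left out, quantile normalization, median centring, cyclic loess, leaving out the dimmest 40% of genes, averaged probe sets, every probe set of the table, eBayes with trend and robust, variances pooled without moderation, and a minimum fold of 1.2.

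The steps were tested on simulated data with 200 of 19938 genes changed. With independent noise, 0% of genes changed 2-fold were recovered, 90.5% of those changed 4-fold and 97.5% of those changed 8-fold, with 0, 14 and 16 false calls. With noise shared by arrays of the same number, sized as in these arrays, 0%, 76.0% and 93.0% were recovered. A fit with the replicate number as a block recovered 100% at each fold under this noise, with 58, 44 and 31 false calls. This noise was drawn from variances already moderated by eBayes, which vary less between genes than unmoderated ones. Recovery in these arrays can therefore be lower, and their block fit passed no gene. Without the block, 0.375% to 0.537% of unchanged genes had an unadjusted p under 0.05 under this noise, and 4.59% to 4.69% with independent noise. The list of other HIF targets, shifted in the simulations, was called by camera with the preset correlation each time and never with an estimated correlation (smallest adjusted p 0.353). Random noise was drawn separately for each gene, so false calls of lists whose genes vary together were not simulated. With the preset correlation, camera also called 1 unshifted list under independent noise at 4-fold, and 1 at 8-fold.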

Results

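Gene expression was profiled in haematopoietic stem cells (HSCs) from the bone marrow of C57BL/6 mice aged 8 weeks. The cells were sorted as lineage-negative, c-Kit-positive and Sca-1-positive, a gate that holds multipotent progenitors as well as stem cells. Wild-type (WT) mice were set against mice labelled Hif1a-/-, to ask how HSCs differ when Hif1a is deleted. Hif1a encodes the oxygen-regulated subunit of the transcription factor HIF-1. There were 2 arrays per genotype, described as biological replicates and numbered 1 and 2 in each. Median log2 signals over all probe sets were 8.31 and 8.19 in WT arrays 1 and 2, and 8.32 and 8.35 in the arrays labelled Hif1a-/-. With 2 arrays per group, the number of arrays limited the precision, and the median standard error of a log2 difference was 0.15.

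Markers of mature myeloid and mast cells separated the arrays numbered 2 from those numbered 1 in both genotypes. The neutrophil and granule list was a median 1.30 log2 units higher in number 2 than in number 1 among WT arrays and 2.52 higher among the arrays labelled Hif1a-/-. The mast cell, basophil and eosinophil list was 1.85 and 1.56 higher, whereas the stem cell list differed by −0.57 and −0.54. Across 19938 genes, arrays of the same number correlated at 0.995 (number 1) and 0.983 (number 2), the WT arrays with each other at 0.966 and the arrays labelled Hif1a-/- at 0.962. Genes are not independent replicates, and these coefficients only describe the arrays. Because of this split, differences between genotypes are also given within each number.

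**Figure D1:**
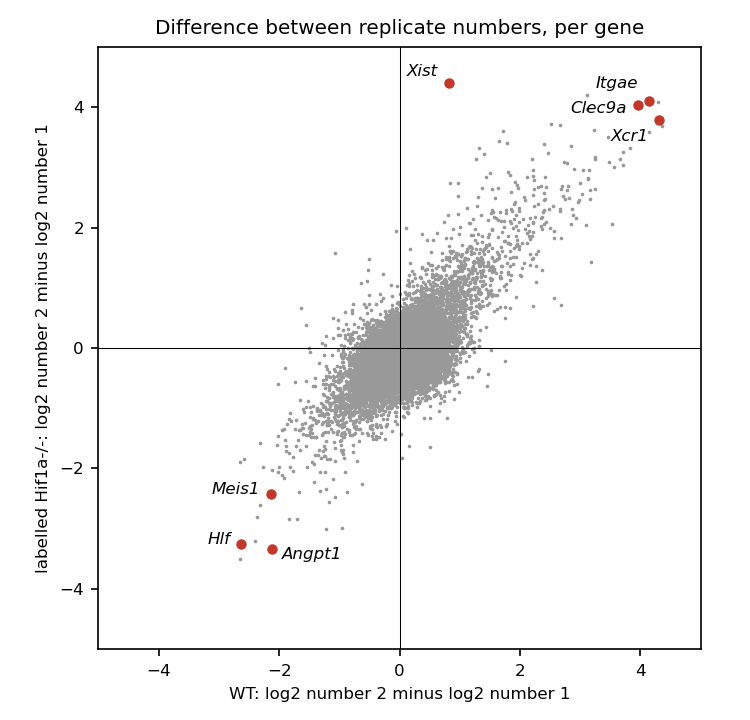
Each point is a gene, with log2 signal of array 2 minus array 1 among WT arrays (x axis) and among arrays labelled Hif1a-/- (y axis). Red points mark genes picked after their values were seen: Xcr1, Clec9a and Itgae were about 4 log2 units higher in number 2 in both genotypes (Itgae 4.14 and 4.11), Hlf, Angpt1 and Meis1 were lower (Hlf −2.64 and −3.25), and Xist was high in a single array.

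No difference in Hif1a itself was detected between the WT arrays and the arrays labelled Hif1a-/-. Its log2 signal was 10.37 and 10.99 in the WT arrays (mean 10.68 ± 0.44, SD, n = 2) and 10.58 and 10.64 in the arrays labelled Hif1a-/- (mean 10.61 ± 0.04, SD, n = 2). The difference was −0.08 log2 units (SE 0.24, 95% interval −0.75 to 0.60), with an unadjusted p of 0.771 in limma. Within the numbers it was 0.20 (number 1) and −0.36 (number 2). Its sign turned under quantile normalization (0.02), under cyclic loess (0.03) and without WT array 2 (0.23). A probe set of a whole-transcript array can cover parts of a gene outside a deleted part, and the labels do not say which part was deleted, so the Hif1a signal does not check the genotype labels. The arrays are therefore named by their label, and each direction between the genotypes follows the labels. Of the 13 genes of the HIF family and oxygen-sensing list, Epas1, which encodes HIF-2α, was 0.17 log2 units higher in the mean (SE 0.18). Epas1 differed by −0.02 in number 1 and by 0.37 in number 2. The HIF prolyl hydroxylase gene Egln3 differed by −0.74 (SE 0.32), with −0.22 in number 1 and −1.26 in number 2. The list as a whole had a median of 0.00 and did not pass camera's test (adjusted p = 0.424).

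No single gene passed the threshold between the genotypes, and the genes with the smallest p-values included several of the B lineage. Of 19938 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.9998. At an unadjusted p under 0.05 there were 145 genes, 109 higher and 36 lower in the arrays labelled Hif1a-/-, or 0.727% of genes. Exchangeable arrays with no change would give 996.9 genes, and simulated unchanged genes with noise shared by array number gave 0.375% to 0.537%. The split was 90 higher and 50 lower under quantile normalization and 88 and 50 under cyclic loess. limma's test against a minimum fold of 1.2 and a test without moderation of the variances also called 0 genes after adjustment. The 145 became 595 without WT array 1, 79 without WT array 2, 622 without array 1 labelled Hif1a-/- and 57 without array 2 labelled Hif1a-/-. The excess of higher genes turned without WT array 1 (177 higher, 418 lower) and without array 1 labelled Hif1a-/- (170 higher, 452 lower). Both arrays labelled Hif1a-/- lay above both WT arrays for 3216 genes and below them for 1660, together 24.5% of genes, where chance gives 33.3% for exchangeable arrays and 21.3% to 21.6% in the simulation with noise shared by number. None of the genes named below for the genotype difference passed the test over all genes.

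Several genes of early B-cell development were higher in the arrays labelled Hif1a-/-. Rag1, a recombinase of antigen-receptor rearrangement, was 1.24 log2 units higher (SE 0.12, 2.36-fold). Vpreb1 and Vpreb3 of the surrogate light chain group were 0.85 and 1.19 higher, and Cd79a, a signalling chain of the B-cell receptor, was 1.06 higher (SE 0.20). The B-lineage transcription factor genes Pax5 and Ebf1 were 0.99 and 1.41 higher. Of the 19 measured B cell markers 16 were higher in the mean, 10 of them with both arrays labelled Hif1a-/- above both WT arrays, with a median of 0.37 log2 units (0.72 in number 1, 0.16 in number 2). Adjusted over the list alone, 7 genes passed, 6 of them higher (Rag1, Vpreb1, Vpreb3, Cd79a, Pax5, Ebf1) and 1 lower (Jchain), against 0 over all genes. camera called the list higher (adjusted p = 2.27e-08), and the call was lost with an estimated correlation between genes (adjusted p = 0.410 with an estimated correlation). In the simulations camera with an estimated correlation also missed the shifted list, other HIF targets, each time (smallest adjusted p 0.353). Random noise there was drawn separately for each gene, so the simulations do not speak for lists whose genes vary together. The estimated correlation was 0.03 for B cell markers. It was 0.87 for oxidative phosphorylation, 0.56 for ribosomal, 0.49 for stem cell and 0.45 for T and NK cell genes. For lists with such high values the loss of the call leaves the call in doubt.

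Immunoglobulin transcripts went the other way. Ighm, the heavy chain of IgM, was lower by 2.66-fold (−1.41 log2 units, SE 0.13), and Jchain, which joins immunoglobulin polymers in plasma cells, was lower by 2.73-fold (−1.45, SE 0.24). Among kappa variable segments, Igkv6-20 differed by −2.95 (SE 0.46), Igkv5-43 by −2.77, Igkv19-93 by −1.82, Igkv10-96 by −1.04 and 1 further segment of the Igkv9 family by −2.14. This set of 11 measured immunoglobulin genes was put together after their values were seen. All 11 were lower in the mean, 8 of them with both arrays labelled Hif1a-/- below both WT arrays, and the median was −1.82 (−1.96 in number 1, −1.72 in number 2). Variable segments resemble each other, and the array does not separate their signals with certainty. None of the 11 passed over all genes.

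**Figure D2:**
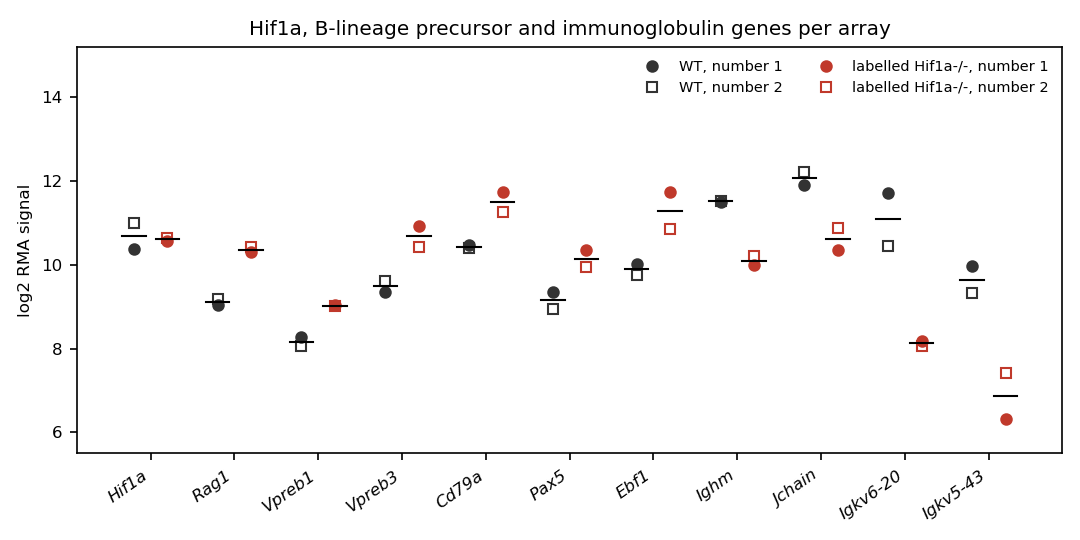
Log2 signal (y axis) of Hif1a, 6 genes of B-cell development and 4 immunoglobulin or plasma-cell genes, with 1 symbol per array (filled circles number 1, open squares number 2) and a bar at each group mean. The 2 arrays labelled Hif1a-/- (red) lie above both WT arrays (black) for Rag1 to Ebf1 and below them for Ighm to Igkv5-43, and the Hif1a signals overlap. Apart from Hif1a, the genes were picked by their values, most by the naming rule that asks for no overlap. The separation shown follows from that choice.

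Other genes that met the naming rule, which asks for a minimum fold and signal, were spread over several functions. Lef1, a transcription factor gene of the Wnt pathway, was 1.18 log2 units higher in the arrays labelled Hif1a-/- (SE 0.15) and the interferon-inducible gene Ifi213 was 1.08 higher (SE 0.11). Slamf6, a lymphocyte surface receptor, was 1.07 higher and the cyclic nucleotide phosphodiesterase gene Pde2a was 1.00 higher. Chst3, Acss1, Gfra1 and E2f2 were 0.70, 0.63, 0.63 and 0.62 higher. On the lower side, Rnf217 differed by −0.80, Egln3 by −0.74, the lysosomal glucosidase gene Gaa by −0.67, and Rrs1, a ribosome assembly factor, and Hmgn5 by −0.63 each. The 12 higher genes came from 32 that met the rule, and the 12 lower genes from 20.

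Interferon-response genes were slightly but broadly higher in the arrays labelled Hif1a-/-. Of 35 measured members 32 were higher, 11 of them in both arrays over both WT arrays, and the median was 0.27 log2 units (0.19 in number 1, 0.29 in number 2). The antiviral genes Mx2 and Rsad2 were 0.59 and 0.42 higher, and Gbp3 differed by −0.13. No member passed over all genes, and 0 passed adjusted over the list alone in limma, with 2 at an unadjusted p under 0.05. camera called the list higher (adjusted p = 9.93e-07), and the call was lost with an estimated correlation (adjusted p = 0.410 with an estimated correlation).

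Targets of HIF were lower as groups, by small amounts. Among 22 glycolysis targets 17 were lower, with a median of −0.18 log2 units (−0.02 in number 1, −0.30 in number 2). The glycolytic enzyme genes Pgam1 and Pfkl differed by −0.44 and −0.24, and Pfkfb4 was 0.22 higher. camera called this list lower (adjusted p = 0.0130; adjusted p = 0.946 with an estimated correlation). Among 33 other HIF targets 25 were lower, with a median of −0.11 (−0.06 in number 1, −0.20 in number 2). Egln3 differed by −0.74 and the mitochondrial gene Higd1a by −0.41, whereas Vegfa, the angiogenic growth factor, was 0.30 higher. camera called this list lower too (adjusted p = 0.00224; adjusted p = 0.946 with an estimated correlation). In either list, 0 genes passed over all genes or adjusted over the list alone in limma, with 0 at an unadjusted p under 0.05. Both calls ended when the dimmest 40% of genes were left out. The glycolysis call ended without WT array 2 (adjusted p = 0.987, direction turned), without array 1 labelled Hif1a-/- (0.251), and under quantile normalization (0.146) or cyclic loess (0.234), and the other-target call ended without WT array 2 (0.0898).

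Genes of respiration, antioxidant defence and translation were also lower as groups, though not within each number. The oxidative phosphorylation list had 30 of 34 members lower and a median of −0.12 log2 units, with 0.15 in number 1 and −0.41 in number 2. Uqcrfs1 of complex III differed by −0.34 and the ATP synthase gene Atp5o by −0.26, and the call (adjusted p = 0.0129) was lost with an estimated correlation (adjusted p = 0.996 with an estimated correlation). Antioxidant and FoxO genes had 20 of 24 members lower and a median of −0.12 (0.03 in number 1, −0.21 in number 2). Sod2 of the mitochondria differed by −0.35, Foxo1 was 0.46 higher, and the call (adjusted p = 0.0359) was likewise lost (adjusted p = 0.946 with an estimated correlation). Cytosolic ribosomal protein genes had 24 of 27 members lower and a median of −0.14 (0.00 in number 1, −0.26 in number 2). Rps19 and Rpl26 each differed by −0.39, and camera's adjusted p was 3.05e-06 (adjusted p = 0.946 with an estimated correlation). Adjusted over the list alone, 0 genes of these 3 lists passed in limma, with 0 at an unadjusted p under 0.05. Against random lists matched on mean signal, the medians lay at percentile 15.56 (oxidative phosphorylation), 9.59 (antioxidant) and 1.37 (ribosomal). The antioxidant median was thus not extreme for its signal level, nor within either number (percentiles 52.03 and 24.57). For oxidative phosphorylation, opposite extremes lay behind the pooled value, with percentile 100 in number 1 and 0.05 in number 2. The ribosomal list lay at percentiles 10.25 and 8.4 within the numbers. The oxidative phosphorylation and antioxidant calls also ended when the dimmest 40% of genes were left out. Without WT array 2 the oxidative phosphorylation list was called higher (adjusted p = 2.12e-07), and without array 1 labelled Hif1a-/- its call ended (0.268). The antioxidant call ended without WT array 2 (0.572), without array 1 labelled Hif1a-/- (0.0522) and without array 2 labelled Hif1a-/- (0.326), and both calls ended under quantile normalization (0.347 and 0.173) and cyclic loess (0.646 and 0.348).

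HSC genes were lower as a group in the arrays labelled Hif1a-/-, while progenitor genes were not called. Of 33 stem cell genes 26 were lower, with a median of −0.20 log2 units (−0.15 in number 1, −0.17 in number 2). The transcriptional repressor gene Gfi1 differed by −0.25 and Ifitm1 by −0.34, and Mllt3 and Hoxb5 were 0.06 higher each. camera called the list lower (adjusted p = 0.0130), and the call was lost with an estimated correlation (adjusted p = 0.996 with an estimated correlation). It also ended, with the direction turned, without WT array 1 (adjusted p = 0.577) and without array 2 labelled Hif1a-/- (0.197). In the multipotent and lymphoid-primed progenitor list of 21 genes, Rag1 alone passed adjusted over the list alone, Blnk was 0.88 higher, the median was 0.03 and camera made no call (adjusted p = 0.443), but called the list higher without array 2 labelled Hif1a-/- (4.999e-06). No stem cell gene passed adjusted over the list alone in limma, with 0 at an unadjusted p under 0.05. The stem cell call also ended when the dimmest 40% of genes were left out.

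Cell cycle, survival and signalling genes gave no call between the genotypes over all 4 arrays. The 43 cell cycle genes had a median of −0.03 log2 units (adjusted p = 0.573), made up of 0.25 in number 1 and −0.32 in number 2, with Mki67 0.22 higher and Cdc20 at −0.34. CDK inhibitors and p53 targets had a median of −0.03 against a mean of 0.01 and a test direction of lower (adjusted p = 0.982), with Cdkn1b 0.15 and Mdm2 0.28 higher. BCL2-family genes had a median of 0.02 (adjusted p = 0.817), with Bcl2l1 0.33 higher. NF-kB and inflammatory genes had a median of 0.08 (adjusted p = 0.684), with Cxcl2 0.34 higher and Nfkbia at −0.30. Immediate-early and stress genes had a median of 0.03, a mean of −0.01 and a test direction of lower (adjusted p = 0.667), with Rhob at −0.51. In the niche signalling and adhesion list Lef1 alone passed adjusted over the list alone, Hes1 was 0.49 higher and Itga6 was at −0.46. That list's median was −0.03, its mean 0.04 and its test direction higher (adjusted p = 0.982). Histone genes had a median of −0.03 (adjusted p = 0.802), and the 28 neighbours of Hif1a on chromosome 12 had −0.09 (adjusted p = 0.0623, 0.0440 under cyclic loess), with Snapc1 at −0.42. With an array left out, camera called cell cycle genes lower without WT array 1 (0.00428) or array 1 labelled Hif1a-/- (0.00194), and higher without WT array 2 (0.0131) or array 2 labelled Hif1a-/- (0.00162) and under cyclic loess (0.0456). It called NF-kB genes higher without array 1 labelled Hif1a-/- (0.00285) and lower without array 2 labelled Hif1a-/- (0.00162), and immediate-early genes lower without WT array 1 (0.00711) or array 2 labelled Hif1a-/- (5.04e-05) and higher without WT array 2 (0.0260).

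Among markers of other cell types, T and NK cell genes were higher as a group, again unevenly. Of 26 members 23 were higher, with a median of 0.22 log2 units (0.03 in number 1, 0.36 in number 2). Cd2 and Cd3d of the T lineage were 0.39 and 0.18 higher, and Gata3 differed by −0.29. The call (adjusted p = 0.0130) was lost with an estimated correlation (adjusted p = 0.996 with an estimated correlation), ended without WT array 1 (0.577) and turned without array 2 labelled Hif1a-/- (0.0273). The T and NK call also ended when the dimmest 40% of genes were left out. Median signals of this list were 7.64 and 8.24 in the WT arrays and 7.83 and 8.735 in the arrays labelled Hif1a-/-, beside 8.56 for all genes. Small nucleolar RNAs, a class of short RNAs that guide RNA modification, were higher for 36 of 51, with a median of 0.16 (−0.12 in number 1, 0.41 in number 2). Snora41 was 0.31 higher, and the call (adjusted p = 0.0129) was lost with an estimated correlation (adjusted p = 0.996 with an estimated correlation). It turned without WT array 2 (0.0463) and ended without array 2 labelled Hif1a-/- (0.447). Adjusted over the list alone, 0 genes of these 2 lists passed in limma, with Snora41 the only member at an unadjusted p under 0.05.

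**Figure D3:**
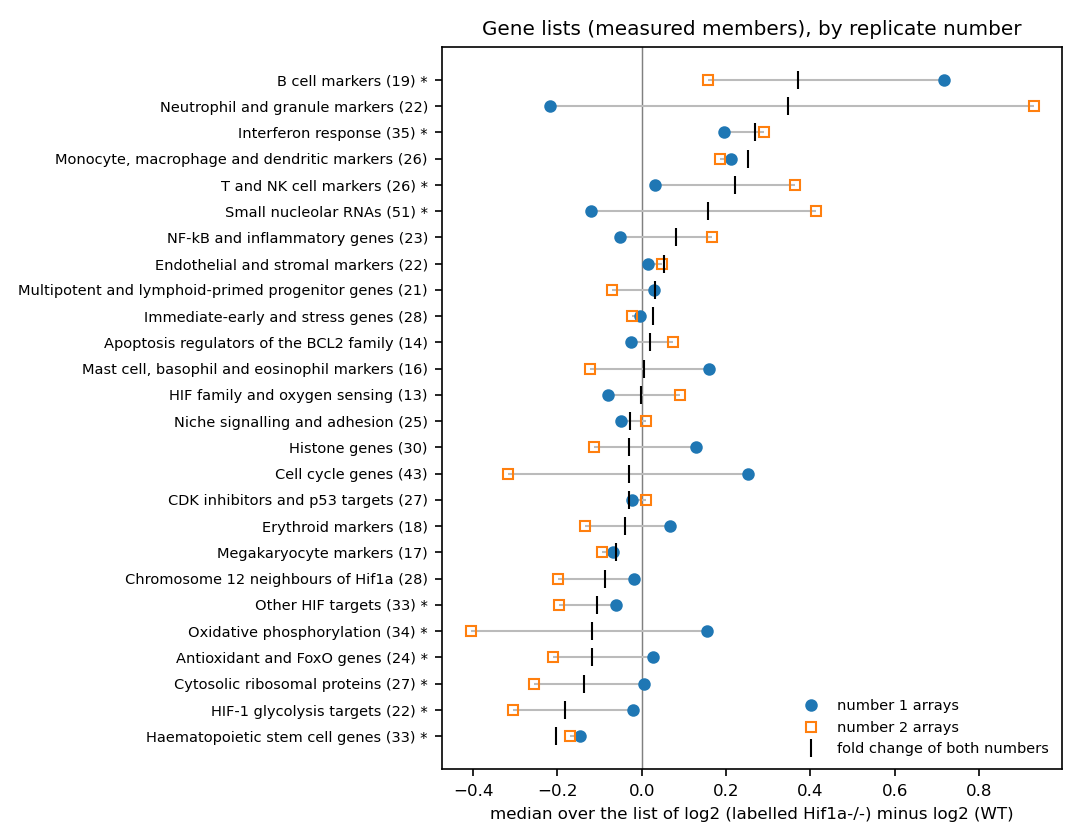
Median log2 difference (arrays labelled Hif1a-/- minus WT, x axis) over the measured members of each of 26 gene lists, with their number in brackets. Blue circles are number 1, orange squares number 2, and black ticks the median of the fold changes over both. Asterisks mark the 10 lists called by camera with the preset correlation. Of these 0 held with an estimated correlation, which also missed the shifted list, other HIF targets, in each simulation.

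The remaining cell-type lists gave no call over all 4 arrays in the fit without the replicate block. Neutrophil and granule markers had a median of 0.35 log2 units and a mean of 0.24 but a test direction of lower (adjusted p = 0.983), with −0.22 in number 1 and 0.93 in number 2. Mmp9 was 0.90 higher and Mpo, the myeloperoxidase gene, was at −0.21. Monocyte, macrophage and dendritic markers had a median of 0.25 (adjusted p = 0.396), with 0.21 in number 1 and 0.19 in number 2, and C1qc was 0.58 higher. With the replicate number as a block, camera called this list higher (adjusted p = 5.64e-05), though not with an estimated correlation (adjusted p = 0.951). Mast cell, basophil and eosinophil markers had a median of 0.01 (adjusted p = 0.983), erythroid markers −0.04 (adjusted p = 0.895), with Gata1 at −0.37, and megakaryocyte markers −0.06 (adjusted p = 0.0905), with F2r at −0.28. Endothelial and stromal markers had a median of 0.05 against a mean of 0.00 (adjusted p = 0.448). With an array left out, several of these lists were called, in a direction that depended on the array. Monocyte, macrophage and dendritic markers were called higher without WT array 2 (1.10e-07) or array 1 labelled Hif1a-/- (2.18e-06) and also without dim genes (0.0170), and lower without WT array 1 (0.00792) or array 2 labelled Hif1a-/- (2.27e-05). Mast cell markers were called higher (1.81e-05 and 0.00303) and lower (0.00116 and 8.92e-05) without the same arrays, and neutrophil markers higher (0.0246 and 2.36e-08) and lower (0.0499 and 1.99e-15). Erythroid markers were called higher without WT array 2 (0.000642) and lower without WT array 1 (0.00234) or array 2 labelled Hif1a-/- (0.00564), and endothelial markers higher without array 1 labelled Hif1a-/- (0.0262). Across the 26 lists tested camera called 10, 4 higher and 6 lower, and fry, which asks whether the genes of a list move on balance in 1 direction, called 0 (smallest adjusted p = 0.398). fry was run without the replicate block and was not tried in the simulations.

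Sex-linked genes differed between the arrays. Xist, expressed from the inactive X chromosome of females, had a log2 signal of 6.94 and 7.76 in the WT arrays and 6.82 and 11.23 in the arrays labelled Hif1a-/-. The Y-linked gene Uty was at 9.19, 8.98, 9.33 and 8.35 in the same order, and Kdm5d at 9.40, 8.98, 9.46 and 8.68. Eif2s3y was at 10.19, 10.09, 10.15 and 9.66, while Usp9y, Zfy1 and Zfy2 lay under 6 on every array. Array 2 labelled Hif1a-/- had signal for Xist and for Y-linked genes together.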

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

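Of the settings tried, only the medians within each array number were chosen after the result was seen. The count of 0 genes after adjustment in limma held under every setting; the 145 genes at an unadjusted p under 0.05 became 478 with the replicate block (265 higher, 213 lower), 39 without the dimmest 40% of genes, 339 with trend and robust, 692 over every probe set, 616 with unmoderated variances, 30 against a minimum fold of 1.2, and 57 to 622 with an array left out. The labels do not say that a number marks a shared day or litter. Across genes, the differences between numbers 2 and 1 of the 2 genotypes correlated at 0.669, the genotype differences of the 2 numbers at −0.0079. With the block camera called 11 lists in place of 10, the added list being monocyte, macrophage and dendritic markers (higher, 5.64e-05), and 0 with an estimated correlation as well. The Hif1a difference turned under quantile normalization (0.015) and cyclic loess (0.026) and spanned −0.38 to 0.23 with an array left out (0.23 without WT array 2). The 10 list calls became 5 without the dim genes, 4 of the 10 and the monocyte list (higher, 0.0170), 0 with an estimated correlation and 0 with fry. With an estimated correlation the adjusted p was 0.410 for B cell and interferon genes, 0.946 for glycolysis, other HIF targets, antioxidant and ribosomal genes, and 0.996 for oxidative phosphorylation, stem cell, T and NK cell genes and small nucleolar RNAs. With fry it was 0.398 for B cell and interferon genes and 0.997 for the other 8 lists. Under quantile normalization, cyclic loess and the dim-gene filter the calls ended for glycolysis (0.146, 0.234, 0.148), oxidative phosphorylation (0.347, 0.646, 0.148) and antioxidant genes (0.173, 0.348, 0.278); the filter alone ended those of other HIF targets, stem cell and T and NK cell genes (0.0699 each). Under cyclic loess cell cycle genes were called higher (0.0456) and the chromosome 12 neighbours lower (0.0440). With an array left out the adjusted p ranged over 0.000697 to 0.987 for glycolysis (turned without WT array 2), 0.00252 to 0.0898 for other HIF targets, 4.26e-16 to 0.268 for oxidative phosphorylation (turned without WT array 2, 2.12e-07), 0.0117 to 0.572 for antioxidant genes, 2.12e-07 to 0.577 for stem cell genes (turned without WT array 1, 0.577, and without array 2 labelled Hif1a-/-, 0.197), 2.38e-08 to 0.577 for T and NK cell genes (turned without array 2 labelled Hif1a-/-, 0.0273) and 4.83e-08 to 0.447 for small nucleolar RNAs (turned without WT array 2, 0.0463). It stayed under 0.05 for B cell (2.22e-12 to 0.00533), interferon (1.00e-07 to 0.00711) and ribosomal genes (8.72e-05 to 0.00998). Lists without a call gained calls in both directions with an array left out: cell cycle (0.00162 to 0.0131), NF-kB (0.00162 to 0.5852), immediate-early (5.04e-05 to 0.0647), erythroid (0.000642 to 0.117), neutrophil (1.99e-15 to 0.0499), monocyte (1.10e-07 to 0.00792) and mast cell genes (1.81e-05 to 0.00303); progenitor genes (4.999e-06 to 0.633) and endothelial genes (0.0262 to 0.938) gained 1 call each, higher. Within number 1 alone the medians turned for oxidative phosphorylation (0.15), antioxidant genes (0.027), small nucleolar RNAs (−0.12) and ribosomal genes (0.0044). The cause of these changes was not tested. Each scaling left the median of all genes within 0.01 of 0, and outside the tested genes 0 of 15618 probe sets passed in limma, with 595 at an unadjusted p under 0.05. How far signals stood over background was not analysed here, and the lone array left in a group when an array was left out was assumed to vary like the other group.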

Other observations

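The tests of swapped labels, of a signal-level trend, of a lower share of the main cell type and of other splits of the arrays were chosen after the result was seen, as were the genes named for the array numbers. The B precursor, plasma cell and extra myeloid gene sets were chosen after the patterns they address were seen, but before their own values were. An exception are 4 B precursor genes, Blnk among them, which also belong to the fixed progenitor list and whose values came with the pattern.

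The arrays numbered 2 carried more signal of myeloid, mast cell and erythroid genes and less of stem cell genes than the arrays numbered 1, in both genotypes. The genes with the largest mean differences include Xcr1, Clec9a and Itgae, known from cross-presenting dendritic cells, which were 4.31, 3.95 and 4.14 log2 units higher among WT arrays and 3.79, 4.03 and 4.11 higher among the arrays labelled Hif1a-/-. Dnase1l3 was 4.30 and 4.09 higher, Chil3 3.12 and 4.21, and Naaa 3.83 and 3.33. All 16 mast cell, basophil and eosinophil genes, 25 of 26 monocyte, macrophage and dendritic genes, 21 of 22 neutrophil genes and 15 of 18 erythroid genes were higher in number 2 in both genotypes. The erythroid list had medians of 0.78 (WT) and 0.51, whereas B cell markers had 0.14 and −0.18 and megakaryocyte markers 0.02 and −0.09.

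Stem cell genes differed the other way, with 27 of 33 lower in number 2 in both genotypes. The stem cell transcription factor genes Hlf and Meis1 differed by −2.64 and −2.14 among WT arrays and by −3.25 and −2.43 among the arrays labelled Hif1a-/-. Angpt1 differed by −2.12 and −3.33, Emcn by −2.40 and −3.21, and Dntt, a polymerase gene of lymphoid progenitors, by −2.27 and −1.97. Of the progenitor list 15 of 21 genes were lower in both genotypes. Immediate-early and stress genes were higher by medians of 0.54 and 0.43.

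Grouping the arrays by number gave 3887 genes at an unadjusted p under 0.05 in limma, and 1344 after adjustment, against 145 and 0 for the genotypes. The third grouping, which crosses both, gave 277 and 0. So 3 of the 3 splits of the 4 arrays gave at least 145 genes, and the highest other was 3887. With 3 splits no share under 0.05 can be reached. The split by number points to a structure of the samples, and the labels give no day, litter or scan for it.

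For the higher mature-cell markers in number 2, a lower share of the main cell type that raised all other markers alike was considered. The megakaryocyte, B cell and endothelial lists stayed under the neutrophil list. The smallest gap from their upper quartiles to its lower quartile was 0.51 log2 units, so these lists did not rise alike. Yet they hold genes that fell steeply in number 2, such as Emcn (−2.40 and −3.21) and Mmrn1 (−2.59 and −1.84). T and NK cell genes, left out of this test, rose by medians of 0.30 (WT) and 0.55 (labelled Hif1a-/-). The test therefore cannot decide on a lower share of the main cell type. A candidate explanation is more mature myeloid cells in the number 2 samples, for which the predicted rise of further myeloid genes was found. Of 12 myeloid genes outside the fixed lists 10 were higher in both genotypes, with medians of 1.16 among WT arrays and 0.97 among the arrays labelled Hif1a-/-. Cst3 went from 12.92 to 14.09 and from 13.21 to 14.05. The lineage-negative gate is meant to remove such cells, and progenitors expressing these genes within the gate stay open.

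For the B lineage, a trend with signal level between the arrays is argued against, since the B cell list lay at percentile 99.74 or higher of level-matched random lists in both numbers. More B-lineage precursor cells in the arrays labelled Hif1a-/- may contribute, though a lineage-negative gate is meant to remove later ones. Of 12 precursor genes outside the B cell list, 11 were higher in the mean and 2 with both arrays above both WT arrays. Their median was 0.60 in number 1 and only 0.17 in number 2. The set holds 4 genes of the fixed progenitor list, so it was only partly unseen. Blnk, one of those 4, was 0.88 higher. Fewer plasma cells could accompany the lower immunoglobulin signal, though the sort for lineage-negative, c-Kit-positive and Sca-1-positive cells may remove such cells. Of 11 plasma cell genes 10 were lower in the mean, yet by medians of only −0.10 in number 1 and −0.26 in number 2. Igkv19-93 stood at 13.40 in the WT arrays. Both cell-type explanations and an effect of the genotype stay open.

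No Hif1a difference was detected (−0.08 log2 units, 95% interval −0.75 to 0.60), and swapped genotype labels in number 1 were considered. A swap would turn the sign of that number's difference (0.20), beside −0.36 in number 2. Hif1a would then be lower in both numbers by small amounts, so a swap could hide only a small loss. The other HIF targets were lower in the array labelled Hif1a-/- of number 1 as well, at percentile 0.9 of level-matched random lists, where genotype labels swapped in number 1 would put them higher. The difference in number 1 rests on 1 array per genotype. Over all 4 arrays the list's shift was within the spread between replicates (unadjusted p = 0.612 with fry, two-sided). As fry was run without the replicate block, that spread includes the difference between numbers, and the value cannot decide. A swap stays open. A probe set that covers parts outside the deleted part stays open too, as the labels do not give the deleted part. Array 2 labelled Hif1a-/-, with Xist at 11.23 and Uty at 8.35, may hold cells of both sexes, for which no further test was run.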
